A study of Mus musculus with 4 samples.

How the data were processed

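Single-cell RNA sequencing had been made from CD45+ DAPI-negative cells sorted from mouse tumours 12 to 13 days after injection. Per the labels' protocols, 10000 cells per mouse and 60000 per condition were sorted, and 5000 cells per condition were targeted. The 4 samples fall into 2 groups of 2 libraries, Sptlc1-KO (knockout) and Sptlc1-KO + Sptlc1 cDNA (cDNA group). The genotype is that of the injected tumour cells, and the profiled cells are host immune cells. The deposited values are UMI counts per gene and cell barcode, per the file headers whole numbers with no normalization. Per the submitters' processing notes, cutadapt, STAR, DESeq2 and limma 3.46 were used with GRCm38, without a role stated for each, and the counter is not named. The barcodes had been called by the authors as deposited, and no further filter was found in the files (32285 genes each).

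Whether the 2 libraries of a group were separate captures was checked from their barcodes and counts, under a rule written before the data were examined, as were the comparisons, gene lists, cell type markers and most alternatives. Because 99.1% and 99.5% of barcodes were shared within the groups, each group was treated as 1 capture of 2 runs, whose counts were averaged and not added. With 1 capture per group no test was run and no p-value is given, and the tests designed for separate captures were not used.

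Cells with at most 10% mitochondrial counts, at least 500 genes and at least 250 counts were kept. Scrublet, run in scanpy 1.11.5 per capture, marked 3 of 2311 knockout and 2 of 5168 cDNA cells at its automatic threshold, which did not work as a doublet filter, and an alternative that removes the top scores at 0.8% per 1000 barcodes was added. Following the study's own steps, which used Seurat 4.0.3, the captures were normalized with SCTransform (sctransform 0.4.2), integrated by anchors on 5000 features, and clustered by Louvain at resolution 1 on 50 principal components in Seurat 5.3.0 under R 4.3.3, giving 25 clusters. The imputation step of the study and its tests across cells were left out. Clusters were named from the fixed markers. After the data had been seen, the naming rule was changed so that clusters 18 and 6 stayed outside the named classes, and both are reported apart. Cluster 18 was of low depth, had Retnlg, Alox15 and Ccr3 among its leading genes, and is called Ccr3-led here. Cluster 6 was led by Ear2. Clusters that met the markers of T cells and NK receptors, or of no T cell subset, were also kept apart. Further work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

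Shares carry exact (Clopper-Pearson) 95% binomial intervals, and their ratios Katz intervals. Expression was compared within classes with at least 50 cells in each capture (CD8 T, CD4 T, Treg, NK, monocyte/macrophage and neutrophil). Counts were summed over the class and scaled to a common total (CPM), with log2 folds of knockout over cDNA and exact conditional binomial 95% intervals. B cells and dendritic cells had too few knockout cells for this. Genes of at least 2-fold were counted among those with at least 100 UMIs in the capture with the higher level. All intervals cover counting error only. A gene at 0 in a capture was set to a floor of 3 counts over the group.

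The 25 lists cover the interferon gamma and type I interferon responses, MHC class I and II, cytotoxic effectors, T cell exhaustion, naive and memory T, regulatory T, T cell activation, tissue repair and suppressive macrophages, inflammatory myeloid genes, lymphocyte recruiting chemokines, hypoxia and glycolysis, proliferation, sphingolipid and glycosphingolipid synthesis, cholesterol synthesis, oxidative phosphorylation, complement and lysosome, dissociation and immediate early genes, the unfolded protein and integrated stress response, and RNA of fibroblasts, epithelial or cancer cells, erythroid cells, neutrophils and macrophages. A member was measured at a mean of at least 10 UMIs. The median log2 fold was set against 10000 random lists of the same size matched on expression in 20 bins, and its interval came from 1000 Poisson draws. A member is called higher or lower when its own interval excludes equality. The symbols Mx1, Aldoa, Cert1 and Ddit3 found no match among the gene names used. Symbols shared by several gene identifiers had been renamed with their identifier, so an unmatched symbol need not be absent from the files. Setting list genes with 0 UMIs to the floor replaced an earlier prior count after the data had been seen.

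Genes were named by a rule. It holds 20 genes fixed in advance (where the class had at least 10 UMIs), the 10 largest and 10 smallest folds in CD8 T cells, NK cells, monocytes/macrophages and neutrophils among genes whose interval lay beyond 1.5-fold with at least 100 UMIs and at least 10% of the level in the highest class, and up to 4 members of each list. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and unnamed genes were left out of the largest and smallest folds. Tff1, Retnlg, Alox15, G0s2, Cxcl2 and the eosinophil genes Ccr3, Prg2 and Ear2 were chosen after their values were seen. Genes that lead clusters are named only to identify these. For some genes with much of their UMIs in 3 cells, that share or the fold without those cells is given. That alternative was redefined after a first version had biased small classes, and now leaves out cells of the capture with the higher level only. Ifng and dividing cells were also measured after thinning each cell to 2000 UMIs, where a dividing cell had transcripts of at least 2 proliferation genes.

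The procedure was tested on simulated data. Counts were Poisson draws from class sums with no spread between cells, so the rates do not cover genes whose UMIs lie in few cells. True folds were corrected for composition only to check interval coverage. Without that correction, 100% of genes with a true 3-fold change reached 2-fold in CD8 T cells, and 44% of those with a true 2-fold change. In NK cells 54% of true 2-fold genes reached it, in monocytes/macrophages 50%, in neutrophils 48%, in CD4 T cells 36% and in Treg cells 50%. The check of unchanged genes was moved to the interval beyond 1.5-fold after it first failed at 2-fold, and 3 of 3634 unchanged genes in neutrophils and 5 of 1258 in Treg cells passed that bound. Alternatives changed 1 choice at a time, except that leaving out the integration also replaced Seurat's Louvain by scanpy's Leiden clustering. They covered the gene and mitochondrial limits, doublet removal, each replicate left out, no integration (scanpy with leidenalg 0.10.2), other resolutions, scaling, UMI minimums, denominators and the sets of cells.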

Results

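Immune cells infiltrating mouse tumours were profiled by single-cell RNA sequencing in 4 libraries. The tumours had been removed 12 to 13 days after injection, and living CD45+ cells were sorted from them. In 2 libraries the genotype was Sptlc1-KO (here the knockout), and in the other 2 it was Sptlc1-KO + Sptlc1 cDNA, in which a cDNA of the gene had been added to the knockout (here the cDNA group). Sptlc1 encodes a subunit of serine palmitoyltransferase, the enzyme of the first step of sphingolipid synthesis. The knockout libraries held 29157257 and 29188077 UMIs in 3368 and 3364 barcodes. The cDNA libraries held 51133167 and 51097698 UMIs in 7150 and 7153 barcodes, where 5000 cells per condition had been targeted. Both libraries of a group had nearly the same barcodes, with 3338 shared in the knockout (99.1%) and 7111 in the cDNA group (99.5%), against 6 between groups. Their summed counts differed by less than sampling noise (chi-square per degree of freedom 0.312 over 13459 genes and 0.287 over 15057 genes). They were therefore averaged and counted as 1 capture, which leaves n = 1 per group, no replicate check and no test. All intervals are 95% intervals for counting error only. After filtering, 2308 knockout cells and 5166 cDNA cells remained, with median depths of 9227 and 6837 UMIs.

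The knockout was made in the injected tumour cells, so Sptlc1 in the sorted host cells does not check the labels. Its level was 34.8 CPM (UMI counts scaled to a common total, 32.7 to 37.1) and 35.5 CPM (33.3 to 37.8) in the knockout libraries, and 28.6 CPM (27.1 to 30.1) and 27.7 CPM (26.2 to 29.2) in the cDNA libraries. The gene (ENSMUSG00000021468) lies on chromosome 13 at 53332748 to 53377397 of GRCm38. The comparison of the 2 captures addresses whether tumours that lack this enzyme hold different immune cells, and Ifng in particular.

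Monocytes and macrophages dominated the knockout capture, while neutrophils and B cells were far more frequent in the cDNA capture. Class names stand for clusters that resemble a cell type by its markers ("CD8 T" for CD8 T-like, for example). The monocyte/macrophage class made up 42.6% (40.6 to 44.7, exact binomial) of knockout cells and 23.4% (22.3 to 24.6) of cDNA cells, a ratio of 1.82 (1.70 to 1.95). Neutrophils made up 5.07% (4.21 to 6.04) and 21.3% (20.1 to 22.4), a ratio of 0.239 (0.198 to 0.287). B cells made up 1.69% (1.20 to 2.30) and 10.1% (9.33 to 11.0), a ratio of 0.167 (0.121 to 0.230). A myeloid cluster led by Ear2, Lyz1 and Retnla, left outside the named classes, made up 12.2% and 3.12% (ratio 3.91, 3.24 to 4.71). A low-depth cluster led by Retnlg, Alox15 and the eotaxin receptor gene Ccr3 held 89 knockout cells (3.86%) and 21 cDNA cells (0.407%). It met 4 of 8 neutrophil and 2 of 6 eosinophil markers, and Retnlg is among the neutrophil markers.

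Among lymphocytes, CD8 T cells made up 9.79% (8.61 to 11.1) of the knockout and 15% (14.1 to 16) of the cDNA capture, a ratio of 0.651 (0.566 to 0.749). Within this class the ratio was 0.249 (0.166 to 0.372) for cluster 12, led by Dapl1, Lef1 and Tcf7. It was 0.752 (0.623 to 0.907) for cluster 5 and 1.04 (0.775 to 1.39) for the dividing cluster 15. The ratio was 1.19 (0.972 to 1.46) for CD4 T cells, 1.24 (0.932 to 1.66) for regulatory T cells (Treg) and 1.16 (0.946 to 1.43) for NK cells, and each of these intervals includes 1. CD8 T, CD4 T and Treg cells with T cells of no named subset, but without the cluster with NK receptors, made up 21.4% and 26.7% of all cells (ratio 0.804, 0.735 to 0.880). As a share of lymphoid cells alone (771 and 2433 cells), the ratio of these T cells turned to 1.13 (1.06 to 1.21) and that of CD8 T cells was 0.918 (0.811 to 1.04). On that base the ratios of CD4 T (1.68, 1.38 to 2.03), Treg (1.75, 1.32 to 2.32) and NK cells (1.64, 1.35 to 2.0) exclude 1. Plasmacytoid dendritic cells were 3 of the knockout and 39 of the cDNA cells (ratio 0.172, 0.0533 to 0.557), and migratory dendritic cells were 10 and 55 (0.407, 0.208 to 0.797). Conventional dendritic cells did not differ detectably as a share of all cells (0.826, 0.596 to 1.15) and were lower as a share of myeloid cells (0.657, 0.474 to 0.909). These shares follow a CD45 sort, filters on genes and mitochondrial RNA, and a depth gap between the captures. With a minimum of 200 genes per cell, neutrophils and the Ccr3-led cells together had a ratio of 0.732 (0.662 to 0.809), against 0.412 (0.358 to 0.474) at the 500-gene minimum.

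**Figure D1:**
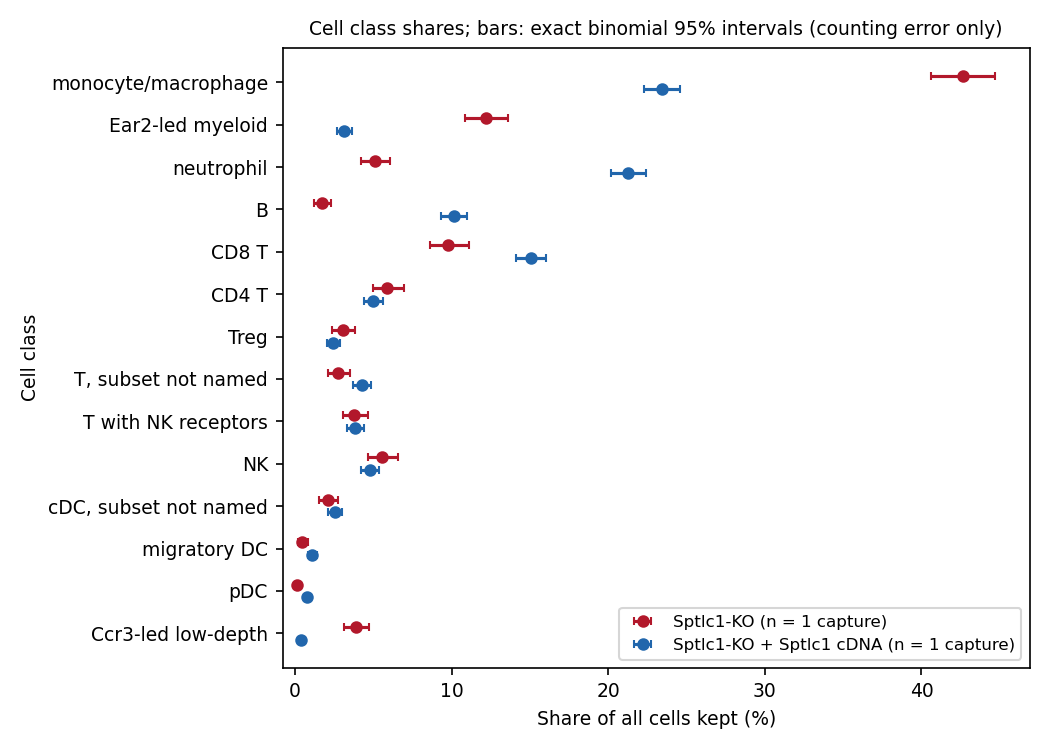
Share of all kept cells (%) in each cell class for the Sptlc1-KO (red) and Sptlc1-KO + Sptlc1 cDNA (blue) captures, 1 capture each, with exact binomial 95% intervals. Monocytes/macrophages reached 42.6% against 23.4%, and neutrophils 5.07% against 21.3%.

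Genes induced by type I interferon, which carry out the antiviral program, were lower in knockout cells of all 6 classes compared. The list's median log2 fold (knockout over cDNA) was -2.96 (-3.21 to -2.53) in CD8 T cells, -2.81 (-3.12 to -2.34) in CD4 T cells, -2.29 (-2.65 to -1.83) in neutrophils, -2.09 (-2.39 to -1.42) in Treg cells, -1.57 (-1.61 to -1.49) in monocytes/macrophages and -1.14 (-1.60 to -0.76) in NK cells. Of the measured members, 18 of 18 in CD8 T cells, 16 of 17 in CD4 T cells, 17 of 17 in neutrophils, 9 of 13 in Treg cells, 18 of 18 in monocytes/macrophages and 9 of 16 in NK cells had intervals below equality, and no member lay above it in any of the 6 classes. Genes induced by interferon gamma, such as the transcription factor gene Stat1 and the T cell attractant genes Cxcl9 and Cxcl10, had medians lower by less. Whether the lists follow separate responses was not tested, so the interferon gamma list alone does not show a lower response to that cytokine. That list's median was -0.84 (-0.93 to -0.77) in monocytes/macrophages, with 26 of 27 members lower, -0.74 (-1.0 to -0.69) in CD4 T cells (16 of 22 lower), -0.61 (-0.80 to -0.51) in CD8 T cells (19 of 25 lower, 1 higher), and -0.53 (-0.92 to -0.46) in neutrophils (12 of 23 lower, 1 higher). Most members had no interval below equality in NK cells (-0.37, -0.56 to -0.20, 7 of 20 lower) and in Treg cells (8 of 22 lower), where the median was -0.19 (-0.38 to -0.06), and -0.02 over members with at least 50 UMIs. The median fold of all measured genes was itself 0.14 in CD8 T, 0.10 in CD4 T, 0.13 in Treg, 0.18 in NK cells, -0.03 in monocytes/macrophages and 0.20 in neutrophils. Relative to it, the type I interferon list lay between -3.10 (CD8 T) and -1.32 (NK), and the interferon gamma list between -0.85 (CD4 T) and -0.32 (Treg).

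Each interferon list lay below all 10000 random lists matched on expression in every class compared, except the interferon gamma list in Treg cells (percentile 1.36). The type I list was also lower within each of the 14 clusters with at least 50 cells of each capture, from -3.04 in cluster 5 (CD8 T) to -0.47 in cluster 2 (monocyte/macrophage, led by Lyve1). The interferon gamma list was at -0.01 (percentile 76.3) within cluster 2 and at -0.14 (percentile 23.5) within cluster 14 (led by Arg1), so it did not stand apart there. Removing the cells with the highest doublet scores brought the type I list in CD8 T cells to -2.28, and restricting it to members with at least 50 UMIs brought it to -0.69 in NK cells.

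**Figure D2:**
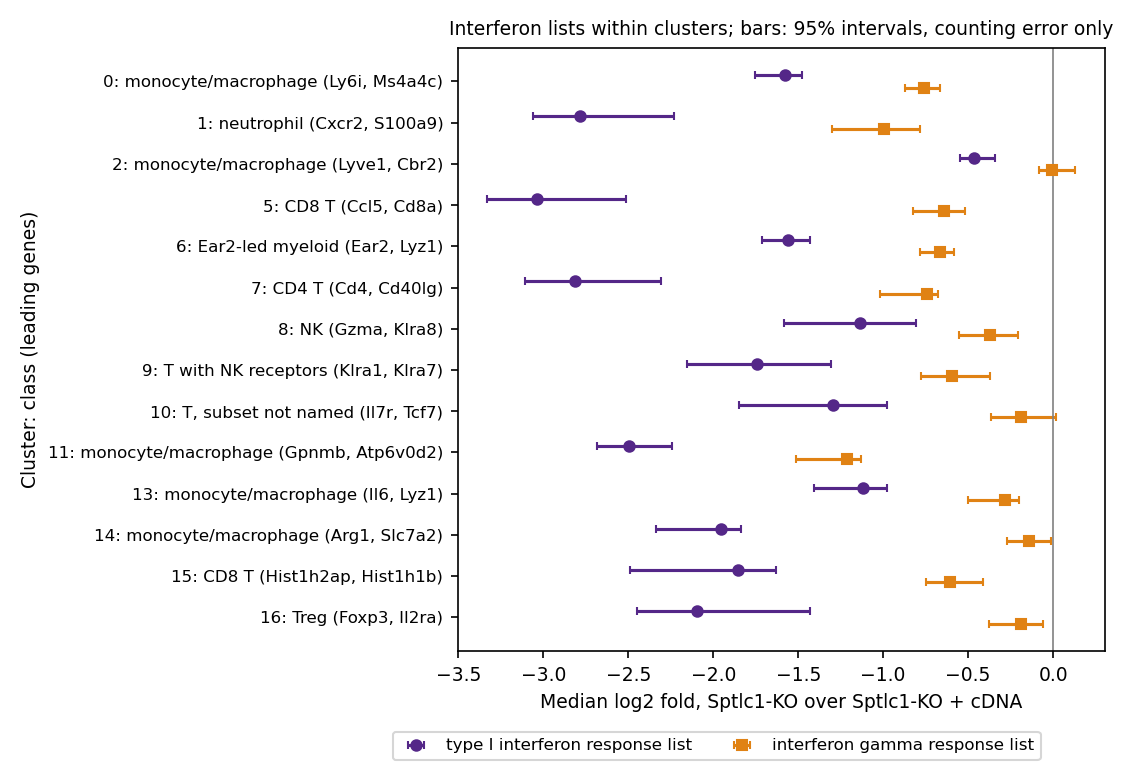
Median log2 fold (Sptlc1-KO over Sptlc1-KO + cDNA, 1 capture each) of the type I interferon (purple) and interferon gamma (orange) lists within each cluster, with 95% intervals for counting error. All 14 type I medians lie below 0, between -3.04 and -0.47.

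Monocytes/macrophages of the knockout capture carried more transcripts of most tissue repair genes and fewer of most inflammatory genes. Retnla, a product of interleukin-4-exposed macrophages, stood at 25487 CPM against 4615 CPM (log2 fold 2.47, 2.45 to 2.48), and was higher within clusters 0, 2, 11, 13 and 14, which hold most of the class. Rnase2a (4.02, 3.90 to 4.14), the transferrin receptor gene Tfrc (2.63, 2.52 to 2.74), the lipid scavenger receptor gene Cd36 (1.57, 1.49 to 1.66) and the haemoglobin scavenger receptor gene Cd163 (1.48, 1.34 to 1.64) were also higher in the class. Within clusters Tfrc was higher in all 5 (1.27 to 3.60), Rnase2a was lower in cluster 13 (-0.77, -1.15 to -0.38) against 3.50 in cluster 2, Cd163 stood at 0.50 in cluster 2 and 0.05 (-0.72 to 0.87) in cluster 13, and Cd36 at 0.30 and 0.20. Of the tissue repair list, 11 of 15 members were higher and 4 lower, with a median of 0.61 (0.53 to 0.63). The interleukin-4-inducible regulator gene Irf4 was higher at 1.42 (1.25 to 1.59). Arg1, which degrades arginine, was lower at -0.66 (-0.69 to -0.63), but higher at 0.54 when cells were clustered without integration, and its direction differed between clusters (1.03 in cluster 0, -0.88 in cluster 14).

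The monocyte genes Ly6c2 (48.4 against 779 CPM, -4.01, -4.12 to -3.90) and Ly6i (-4.96, -5.31 to -4.64) were lower, as were the inflammatory cytokine gene Il1b (396 against 1446 CPM, -1.87, -1.91 to -1.83) and the neutrophil attractant gene Cxcl3 (-4.31, -4.76 to -3.90). Of the inflammatory list, 11 of 14 members were lower and 2 higher, with a median of -1.49 (-1.54 to -1.43). Among interferon targets, Isg15 stood at 46.9 against 391 CPM (-3.06, -3.18 to -2.95), Irf7 at -2.54 (-2.64 to -2.44), Cxcl10 at -3.50 (-3.64 to -3.37), Cxcl9 at -2.18 (-2.26 to -2.10), Stat1 at -0.93 (-0.99 to -0.86) and the checkpoint ligand gene Cd274 at -0.93 (-1.05 to -0.81). The receptor gene Ifngr1 did not differ detectably in the class (-0.02, -0.09 to 0.04) but went both ways within clusters, 0.32 in cluster 0 and -0.26 in cluster 2. Irf1 stood at -0.20 (-0.28 to -0.12), with -0.99 in cluster 11 and 0.20 in cluster 2. Hypoxia and glycolysis genes were lower, 15 of 17 members (median -0.55, -0.60 to -0.46), among them the glucose transporter gene Slc2a1 (45.1 against 90.0 CPM). Cholesterol synthesis genes were lower too, 9 of 12 (-0.47, -0.56 to -0.37). The sphingolipid synthesis list was slightly higher (0.33, 0.23 to 0.42, 10 of 18 members higher and 5 lower), with the ceramide-forming desaturase gene Degs1 at 0.82 (0.73 to 0.92) and Sptlc1 itself at 0.34 (0.17 to 0.51). MHC class I genes stood at -0.42 (-0.48 to -0.36), 8 of 12 lower, while MHC class II genes stood at 0.05 (0.03 to 0.07), and H2-Ab1 at -0.01, which turned to 0.02 under median-of-ratios scaling.

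The largest cluster of this class differed between the captures. Cluster 2 (led by Lyve1, Cbr2 and Gas6) held 392 of 984 knockout cells, and cluster 0 (led by Ly6i, Ms4a4c and Cxcl9) held 557 of 1209 cDNA cells. Within cluster 0, Ly6c2 stood at -3.04 (-3.18 to -2.90), Il1b at -1.64 (-1.72 to -1.56) and Isg15 at -2.70 (-2.90 to -2.50). Within cluster 2, Ly6c2 stood at -0.81 (-1.08 to -0.53), Il1b at -1.93 (-2.09 to -1.76) and Isg15 at -1.02 (-1.24 to -0.80), and Cxcl9 at 0.15 (-0.17 to 0.49). Without integration the whole-class folds were larger for Il1b (-2.90), Cxcl10 (-4.42) and Cxcl3 (-5.27). Transcripts of the epithelial list also moved with the group in this class (list median -3.90, -4.65 to -3.09), and so did neutrophil free RNA (-2.56, -2.82 to -1.77) and fibroblast RNA (1.75, 1.38 to 2.08). The epithelial list is not exclusive to epithelial cells, as the plasmacytoid dendritic cell cluster met 2 of its 6 markers.

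**Figure D3:**
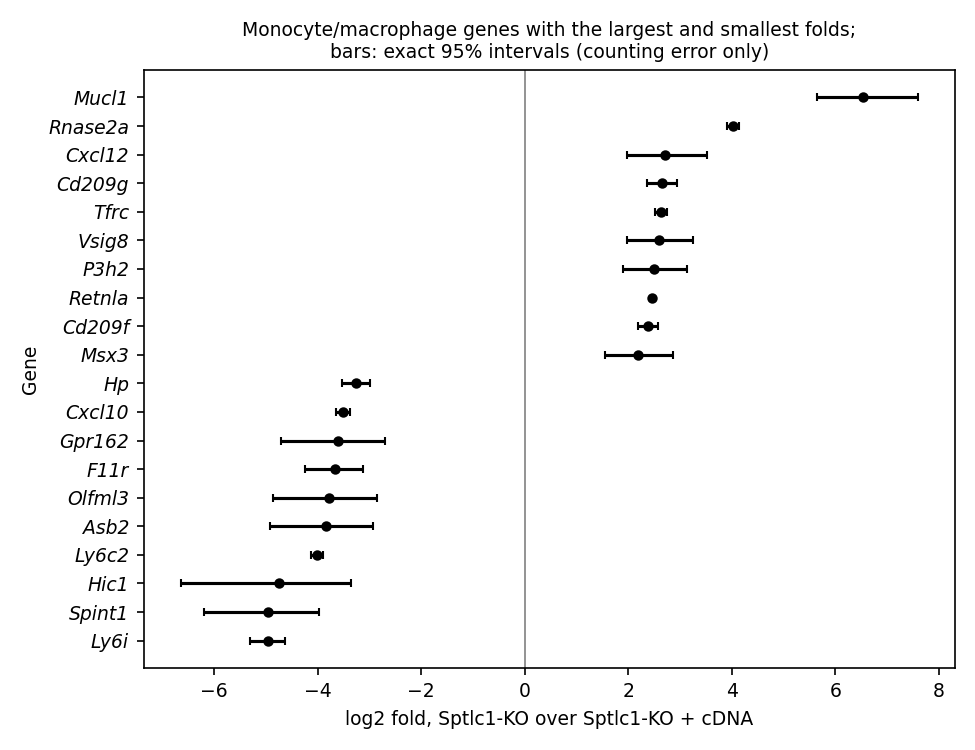
Monocyte/macrophage genes with the largest and smallest log2 folds (Sptlc1-KO over Sptlc1-KO + cDNA, 1 capture each), with exact 95% intervals for counting error. Ly6i and Ly6c2 lie at -4.96 and -4.01 and Rnase2a at 4.02, while 3 cells hold 84.8% of the knockout UMIs of Mucl1.

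Neutrophils of the knockout capture, 117 cells against 1098, had fewer transcripts of chemokines and alarm cytokines. The neutrophil attractant gene Cxcl3 stood at 190 against 3246 CPM (log2 fold -4.11, -4.44 to -3.79), and was also lower within cluster 1 (-3.43, -3.98 to -2.93), which it does not lead. Cxcl1 (-3.21, -4.28 to -2.33), Il1a (-2.76, -3.37 to -2.20), Ccl3 (-1.97, -2.08 to -1.86) and Il1b (-0.50, -0.54 to -0.45) were lower as well. Within cluster 1 they stood at -1.62 (-3.09 to -0.47), -2.97, -1.11 (-1.33 to -0.89) and -0.58 in the same order. Of the inflammatory list, 9 of 12 members were lower and 2 higher (median -1.24, -1.41 to -1.08). The interferon-inducible genes Slfn5 (-2.76, -3.29 to -2.27) and Cxcl10 (-2.65, -3.15 to -2.19) were lower, and Stat1 did not differ detectably in the class (-0.14, -0.37 to 0.08) but was lower within cluster 1 (-0.39, -0.62 to -0.16). Hypoxia and glycolysis genes were lower, 10 of 16 (-0.59, -0.73 to -0.45), although the lipid droplet gene Hilpda stood at -1.41 in the class and at 0.91 within cluster 1. Tgfbi (1.69, 1.45 to 1.94), an extracellular matrix protein gene, and Ckap4 (1.97, 1.63 to 2.29) were higher. Granule genes of immature neutrophils such as Ngp and Camp had 99.9% and 99.95% of their knockout UMIs in 3 cells, and are not read as a difference. Cluster 1 (led by Cxcr2) held 74 knockout and 557 cDNA cells, and cluster 3 (led by Cxcl3 and Ccl3) 43 and 541.

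CD8 T cells of the knockout capture showed lower interferon-stimulated transcripts beside higher activation transcripts. The antiviral gene Ifit3 stood at 4.06 against 79.1 CPM (log2 fold -4.29, -5.35 to -3.40) and Stat1 at 213 against 418 CPM (-0.97, -1.11 to -0.84), while Irf1, a direct interferon gamma target, was higher at 0.46 (0.28 to 0.64, 0.32 relative to the class median). The costimulatory receptor gene Icos (1.11, 0.98 to 1.24), the checkpoint gene Ctla4 (361 against 152 CPM, 1.25, 1.12 to 1.37), the antigen receptor-induced Irf4 (1.25, 0.96 to 1.54) and Rora (1.62, 1.46 to 1.78) were higher, also within clusters 5 and 15. Of the activation list, 7 of 11 members were higher and 2 lower (median 0.62, 0.49 to 0.72). The costimulatory receptor gene Tnfrsf9 (-1.59, -1.98 to -1.22) and the chemokine genes Xcl1 (-1.56, -1.73 to -1.39) and Ccl1 were lower; for Ccl1, 3 cells held 43.1% of the cDNA UMIs, and the fold was -7.50 without them. Cytotoxic effector genes showed no common direction, with 6 of 17 higher and 7 lower (-0.06, -0.15 to 0.11), and Gzmb was lower at -0.54 (-0.63 to -0.45) and Prf1 at -0.25 (-0.43 to -0.07). Exhaustion genes likewise went both ways, 5 of 14 higher and 6 lower (0.03, -0.25 to 0.19), with the checkpoint receptor gene Pdcd1 at -0.32 (-0.52 to -0.13) and Tox at -0.07 (-0.25 to 0.10). Cholesterol synthesis genes were lower, 9 of 12 (-0.83, -1.15 to -0.51), among them Fdps (-2.51, -3.40 to -1.74).

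The CD8 T class was made of cluster 5 (led by Ccl5 and Gzmk, 136 knockout and 405 cDNA cells), cluster 12 (led by Dapl1, Lef1 and Tcf7, 26 and 234) and the dividing cluster 15 (64 and 138). Naive and memory genes had a median of -0.29 (-0.42 to -0.19, 6 of 10 lower) that turned to 0.58 without replicate 1 of the cDNA group and to 0.64 without integration. The CD8 T share ratio was 0.822 and 0.825 in these settings, against 0.651 as reported. The class thus held different cells there, and the change is not one between replicates. Tcf7, a memory T cell regulator, stood at -0.03 (-0.20 to 0.13), at 1.62 (1.30 to 1.94) within cluster 5, and at 1.00 in the class without replicate 1 of the cDNA group. Neutrophil transcripts were lower in CD8 T cells (list median -6.47, -7.07 to -5.64), as were epithelial transcripts (-4.03, -4.78 to -3.41), but few cells hold most of both. In the cDNA capture 3 T cells held 93.5% of the UMIs of S100a8 and S100a9, and 1 CD8 T cell held 88.4% of the epithelial UMIs, without which these stood at 24.9 CPM, against 5.49 CPM without the top cell of the knockout. Genes that tissue dissociation can induce were higher in knockout cells of every lymphoid class compared, with medians of 0.43 in CD8 T, 0.59 in CD4 T, 0.67 in Treg and 0.67 in NK cells. Their bearing on the higher activation transcripts was not tested.

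CD4 T cells of the knockout capture combined lower interferon transcripts with higher transcripts of activation, and Treg cells had lower type I interferon transcripts. In CD4 T cells, Isg15 stood at 37.1 against 260 CPM (log2 fold -2.83, -3.35 to -2.35), Stat1 at -1.13 (-1.35 to -0.92) and the chemokine gene Ccl5 at 582 against 1992 CPM (-1.78, -1.90 to -1.65). Irf1 did not differ detectably there (0.16, -0.17 to 0.48). The Ccl5 fold was -1.17 without replicate 1 of the knockout, -1.14 without replicate 2 of the cDNA group and -1.05 at a clustering resolution of 2. Ctla4 (1.09, 0.96 to 1.21) and the antigen receptor-induced nuclear receptor genes Nr4a3 (1.24, 1.07 to 1.41) and Nr4a2 (1.12, 0.94 to 1.30) were higher, and 7 of 11 activation genes were higher with none lower (median 0.52, 0.42 to 0.64). In the same cells the dissociation and immediate early list was higher by about as much (0.59, 0.51 to 0.73, 11 of 16 higher and 2 lower). Whether tissue handling also raised the activation genes was not tested. Hypoxia and glycolysis genes were higher, 11 of 15 with none lower (0.60, 0.48 to 0.83), among them Pgk1 (1.05, 0.87 to 1.23). Cytotoxic effector genes were lower in both classes, 9 of 13 in CD4 T cells with 3 higher (-0.90, -1.14 to -0.65) and 6 of 10 in Treg cells (-0.97, -1.35 to -0.70). In Treg cells, the lineage regulator Foxp3 stood at 907 against 600 CPM (0.60, 0.40 to 0.79), Ctla4 at 0.60 (0.49 to 0.71) and the interleukin-33 receptor gene Il1rl1 at 1.55 (1.14 to 1.97). Treg activation genes did not stand apart from random lists (median 0.36, 0.20 to 0.53, 5 of 9 higher and 1 lower, percentile 97.49). Isg15 was lower in Treg cells at -2.40 (-3.27 to -1.63), and Stat1 did not differ detectably (-0.02, -0.23 to 0.18). The Treg comparison rests on 70 and 126 cells.

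NK cells of the knockout capture (128 against 246 cells) had more Prf1, the pore-forming effector gene, at 1304 against 768 CPM (log2 fold 0.76, 0.66 to 0.87), and less Gzmb, a granzyme gene, at 498 against 1045 CPM (-1.07, -1.22 to -0.93). Of the cytotoxic list, 6 of 17 members were higher and 6 lower (median 0.15, -0.01 to 0.28, -0.03 relative to the class median). Xcl1, an attractant of dendritic cells, was lower (-1.34, -1.49 to -1.20), as was the aryl hydrocarbon receptor gene Ahr (-2.15, -3.06 to -1.36). Gzmc was lower at -5.57, but 3 cells held 74.5% of its cDNA UMIs and the fold without them was -3.67. Gzmd had 0 UMIs in the knockout and 273 in the cDNA capture, at least 37.3-fold lower against a floor of 3 counts over the group, but 3 cells held 100% of them. The heat shock genes Hspa1a (2.09, 1.72 to 2.48) and Hspa1b (1.98, 1.71 to 2.26) and the quiescence regulator gene Klf2 (1.30, 1.01 to 1.60) were higher. Ugcg, the glucosylceramide synthase gene, was higher in these host cells (0.96, 0.85 to 1.07). Stat1 (-0.63, -0.89 to -0.37) and the immunoproteasome gene Psmb8 (-0.79, -0.99 to -0.59) were lower.

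**Figure D4:**
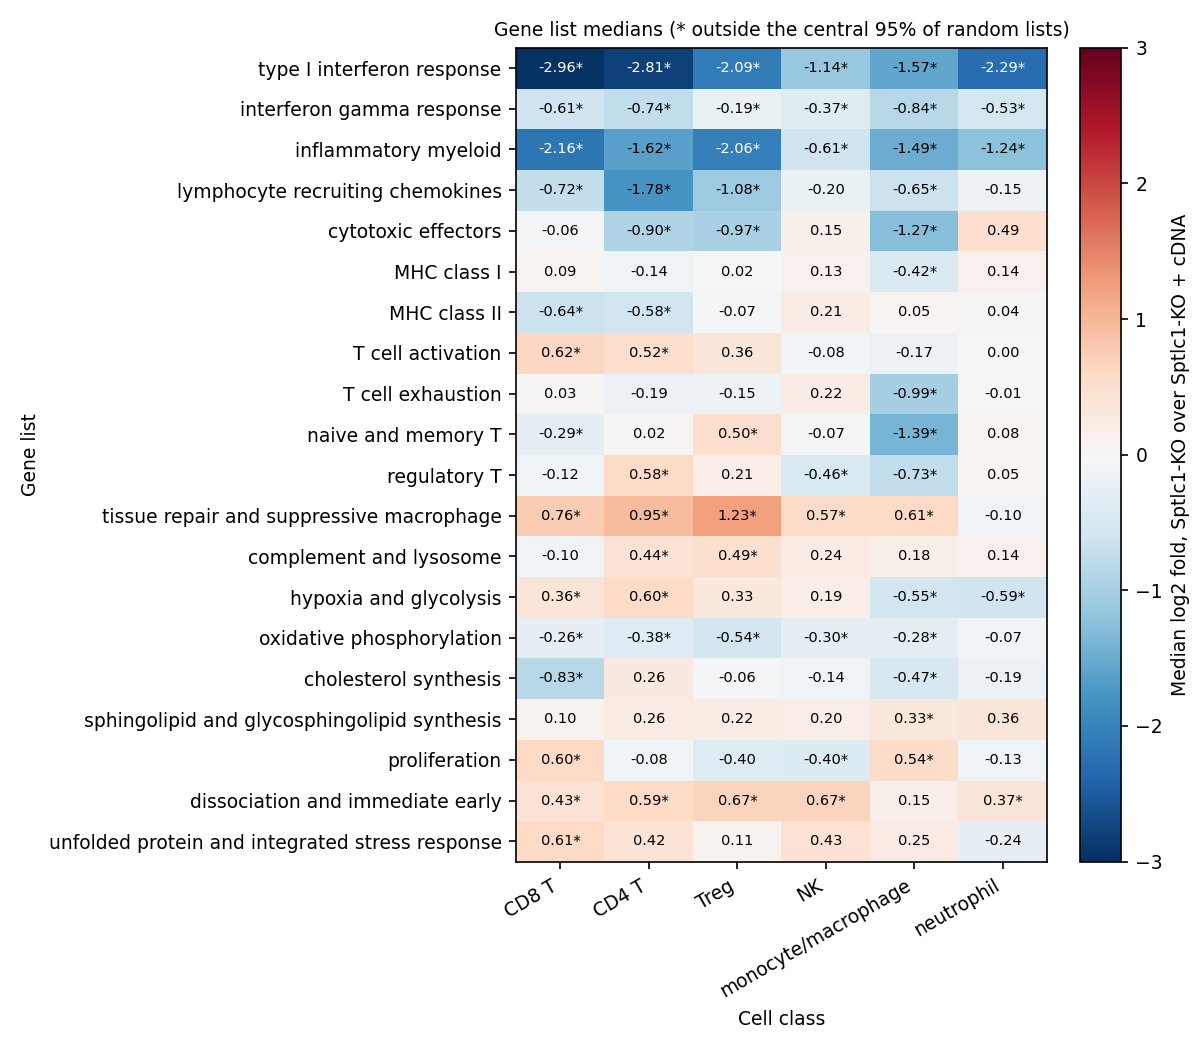
Median log2 fold (Sptlc1-KO over Sptlc1-KO + cDNA, 1 capture each) of 20 gene lists in 6 cell classes; a star marks medians outside the central 95% of random lists. The type I interferon list is lower in all 6 classes, from -2.96 to -1.14.

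Ifng transcript levels were higher in CD8 and CD4 T cells of the knockout capture, while the NK comparison rests on few cells. The gene (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) encodes the cytokine interferon gamma. In CD4 T cells it stood at 405 CPM (367 to 445) against 242 (220 to 266), a ratio of 1.67 (1.46 to 1.91), and in CD8 T cells at 191 CPM (174 to 209) against 138 (130 to 146), a ratio of 1.38 (1.24 to 1.54). Within CD8 T cells the ratio was 1.32 (1.14 to 1.52) in cluster 5 and 1.00 (0.846 to 1.18) in the dividing cluster 15, and 1.76 (1.53 to 2.03) without cluster 15. That last ratio, and the shares of the whole class below, also depend on the mix with cluster 12, which is 26 of 162 knockout and 234 of 639 cDNA cells outside cluster 15. Without replicate 1 of the cDNA group the CD8 T ratio was 1.14, and without replicate 2 of that group the CD4 T ratio was 2.47. The cells of the classes changed too, with share ratios of 0.822 against 0.651 in CD8 T and 0.914 against 1.19 in CD4 T. In NK cells it was 1.01 (0.833 to 1.22), where 3 cells held 65.7% of the cDNA UMIs, and in Treg cells 0.525 (0.128 to 1.63). After thinning each cell to 2000 UMIs, 25.3% of knockout and 14.9% of cDNA CD8 T cells had an Ifng UMI (ratio 1.71, 1.29 to 2.26), 34.6% and 22.3% of CD4 T cells (1.55, 1.12 to 2.15), and 22.7% and 9.92% of NK cells (2.28, 1.39 to 3.75). Unthinned, the shares were 56.6% and 38.7%, 48.5% and 38.3%, and 46.9% and 33.3%. In the T cells with NK receptors the Ifng ratio was 0.958 (0.645 to 1.40). Their thinned shares were 9.41% of knockout and 10.2% of cDNA cells, and their unthinned shares 17.2% and 33.5%. Thinning left out 1 and 3 CD8 T cells, 0 and 0 CD4 T cells, and 0 and 4 NK cells. Background was lower in the classes that should lack the transcript. In thinned B cells, 0 of 39 knockout cells had a UMI, which allows up to 9.03%, against 1.17% of cDNA cells, with median depths of 7266 and 4622 UMIs, beside 8720 and 8258 in CD8 T cells. In thinned neutrophils the shares were 3.74% and 0.468%, with median depths of 3226 and 3776. Unthinned, neutrophils stood at 13.8 against 2.74 CPM on 6 and 12 UMIs (ratio 5.04, 1.55 to 14.5), the same direction as in CD8 and CD4 T cells. Monocytes/macrophages stood at 1.18 against 1.70 CPM (0.703, 0.369 to 1.30). Background in neutrophils was thus not equal between the captures, and its part in the T cell ratios was not tested.

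**Figure D5:**
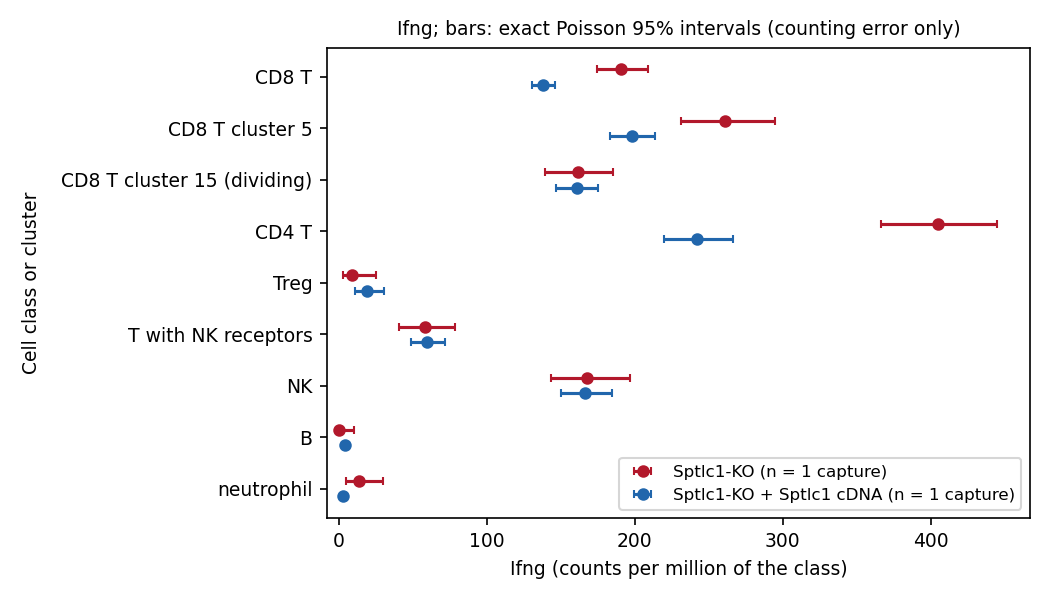
Ifng CPM in each cell class or cluster for the Sptlc1-KO (red) and Sptlc1-KO + Sptlc1 cDNA (blue) captures, 1 capture each, with exact Poisson 95% intervals. CD4 T cells reached 405 against 242 and CD8 T cells 191 against 138, while NK cells stood at 168 and 167.

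Dividing cells made up more of the CD8 T class in the knockout capture as clustered here, but not under all alternatives. As a share of all cells, the dividing cluster 15 made up 2.77% of the knockout and 2.67% of the cDNA capture (ratio 1.04, 0.775 to 1.39). Cluster 12, led by Dapl1, Lef1 and Tcf7, made up 1.13% and 4.53% (0.249, 0.166 to 0.372). The values of the whole class therefore also depend on the mix with cluster 12. After thinning, 40.4% (34.0 to 47.2) of knockout and 28.6% (25.4 to 31.9) of cDNA CD8 T cells had transcripts of at least 2 of the proliferation list's 18 genes, a ratio of 1.42 (1.17 to 1.72). The interval included 1 without replicate 1 of the cDNA group (1.16, 0.959 to 1.41), without integration (1.17, 0.972 to 1.42), at resolution 0.5 (1.19, 0.983 to 1.44) and unthinned (1.04, 0.960 to 1.13). The proliferation list's median was 0.60 (0.54 to 0.66, 17 of 18 members higher), with Mki67 at 0.63 (0.54 to 0.72) and Top2a at 0.76 (0.67 to 0.85), and -0.16 without cluster 15. The ratio of dividing cells did not differ detectably from 1 in CD4 T (1.19, 0.783 to 1.80), Treg (1.06, 0.586 to 1.91) and NK cells (0.921, 0.556 to 1.53). With up to 20% mitochondrial counts it was 0.725 (0.430 to 1.22) in CD4 T and 0.481 (0.265 to 0.873) in NK cells. In monocytes/macrophages it was 1.40 (1.11 to 1.78), but the class's proliferation list (0.54, 0.43 to 0.63) turned to -1.02 without integration. In B cells, taken as background, 2.56% and 6.43% reached the threshold. Free RNA of dividing cells was not measured apart, so the per-cell calls leave it open.

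Counts of genes with at least a 2-fold difference describe the size of the gap between these captures. In monocytes/macrophages, 158 genes were higher and 423 lower of 8974 with at least 100 UMIs. In CD8 T cells the counts were 74 and 204 of 5569, in CD4 T cells 55 and 70 of 2423, in NK cells 28 and 32 of 2438, in neutrophils 26 and 191 of 2457, and in Treg cells 9 and 35 of 1096. The minimum applied in the capture with the higher level, and the cDNA capture held more UMIs in every class (4383000 against 435000 in neutrophils). A gene could therefore be counted as lower at a smaller CPM than as higher, so the split of directions is partly built in. Without the 3 cells holding most UMIs of each gene, they were 104 and 343, 20 and 120, 10 and 50, 9 and 14, 3 and 139, and 2 and 14 in the same order. The higher counts moved with the setting. In CD8 T cells they were 38 without replicate 1 of the cDNA group, 42 without integration and 39 at resolution 0.5. They were 218 there after removal of the top doublet scores. CD4 T cells had 99 without replicate 1 of the knockout, 103 without replicate 2 of the cDNA group and 109 at resolution 2. Leaving out a library also repeats the clustering, which can change the cells of a class. Median-of-ratios scaling moved the split of higher and lower genes to 33 and 275 in CD8 T cells, 34 and 81 in CD4 T cells and 18 and 79 in NK cells. Counting noise alone put 137 of 3634 unchanged simulated genes past 2-fold in neutrophils and 20 of 1258 in Treg cells.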

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

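For the interferon genes, the tests of free RNA and of cluster mix were planned before their results were seen. The gene minimum, the integration and the scaling were planned as alternatives, but their use as tests, and all other tests below, were chosen after.

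Barcodes left out of the comparisons, with fewer than 500 genes and at most 10% mitochondrial counts, made up 7.13% (6.28 to 8.06) of the knockout and 2.01% (1.70 to 2.36) of the cDNA barcodes. Some transcripts of eosinophils stood higher in those of the knockout capture. Ccr3, the eotaxin receptor gene, reached 835 CPM against 455 (ratio 1.85, 1.31 to 2.66), Prg2, a granule protein gene, 192 CPM against 76.7 (2.35, 1.06 to 5.92), and Ear2, an eosinophil ribonuclease gene, 177 CPM against 40.9 (4.25, 1.49 to 16.7). In kept cells Ear2 stood at 752 and 163 CPM, so its transcripts there can come from other cells. Siglecf did not differ detectably (1.82, 0.692 to 5.60). Alox15 was higher too (1226 against 629 CPM), as was the neutrophil gene S100a8 (2.06, 1.28 to 3.43), while Retnlg was similar (5529 against 5051). The neutrophil markers G0s2 (1694 against 1692 CPM) and Cxcl2 (3462 against 3440 CPM) were also abundant and similar, so these barcodes are not assigned to a cell type. S100a8 was found in fewer knockout than cDNA barcodes (10, 4.20%, against 18, 12.6%), and S100a9 did not differ detectably (1.38, 0.883 to 2.19). Epx and Ear1 had 0 UMIs in both.

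Some lists moved in opposite directions in different classes, and these differences were not tested. The difference of median log2 folds was 1.88 for naive and memory genes (Treg minus monocytes/macrophages), 1.31 for regulatory T genes (CD4 T minus monocytes/macrophages), 1.20 for hypoxia and glycolysis (CD4 T minus neutrophils) and 1.00 for proliferation (CD8 T minus NK). The CD4 T median of regulatory T genes turned to -0.06 without integration and to -0.27 without markers of another class, and the CD8 T median of proliferation to -0.16 without the dividing cluster. For RNA of other cells it was 7.53 for neutrophil transcripts (neutrophils minus CD8 T), where 3 T cells held 93.5% of the cDNA UMIs of S100a8 and S100a9, and 1.06 for macrophage transcripts (Treg minus CD8 T), where the CD8 T median of -0.37 turned to 2.05 under doublet removal. Neither is read as a difference.

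Genes induced by type I interferon were lower in knockout cells of the 6 classes compared. Free RNA of macrophages in lymphocytes was argued against, since the ratio of T cell to macrophage CPM was 38.9 times as high for the type I list as for the highest macrophage gene in the cDNA capture. A different mix of clusters was argued against as the whole cause by a median of -1.80 over 14 single clusters, and scaling by a highest class median of -1.32 under median-of-ratios. In monocytes/macrophages a different mix stays open as part of the cause for both interferon lists. The type I median was -0.47 in cluster 2, against -1.57 in the class. The interferon gamma median was -0.01 in cluster 2 and -0.14 in cluster 14. The genotype of the tumour cells may underlie the difference, but with 1 capture per genotype it cannot be told apart from anything else that differed between the captures.

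Neutrophils were rarer and macrophages more frequent in the knockout capture. The integration was argued against as the whole cause, since the neutrophil ratio was 0.237 without it. At a minimum of 200 genes the neutrophil ratio was 0.239, but this cannot decide on the gene minimum. The naming rule can keep low-depth clusters out of the neutrophil class. At that minimum the Ccr3-led cells went from 89 to 298 in the knockout and from 21 to 107 in the cDNA capture. For granulocytes as a whole much depends on the gene minimum and on the naming of the Ccr3-led cells, as neutrophils and Ccr3-led cells together went from 0.412 to 0.732. No deposited barcode had fewer than 500 UMIs, so cells below that depth could not be examined. The genotype may contribute, but 1 capture per genotype leaves it not separable from the capture.

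Epithelial transcripts were lower in the knockout capture, at 258 against 3680 UMIs (9.36 against 76.1 CPM, ratio 0.123, 0.108 to 0.140), in 6.02% against 17.1% of cells, while B cells were too few to tell (3 of 39 against 27 of 524). Without the 2 cells with most of them in each capture the ratio was 0.219 (0.190 to 0.252), which argues against single cells as the whole cause. Less free RNA in the knockout capture stays open, since over their ratio in all kept cells the ratio in T cells was 0.758 for macrophage genes, but for S100a8 and S100a9 it was 0.0410, and 0.543 (0.344 to 0.818) without the 3 top cells of each capture. The gap differed by gene, with Epcam at a ratio of 0.443 and Cdh1 at 0.483, while Krt19 had 1.5 against 977.5 UMIs, Krt8 0 against 329 without those cells, and Tff1, chosen after its values were seen, was found in 2 of 984 and 199 of 1209 monocytes/macrophages. The plasmacytoid dendritic cell cluster (3 knockout and 39 cDNA cells) met 2 of the 6 epithelial markers, so the list is not exclusive to epithelial cells. RNA taken up from tumour cells that differ by genotype might contribute, but 1 capture per genotype leaves this open.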

How the results depend on the processing

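The doublet-rate removal, the sets without the 3 top cells, without the dividing cluster and with the Ear2-led cluster were chosen after the results were seen, and all other alternatives were planned.

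The type I and interferon gamma lists kept their direction in 6 classes under all alternatives run. Over these 12 pairs of list and class the alternatives gave 172 values, of which 18 lay outside the interval of the reported one. Of 16 share ratios, 11 kept their side under all alternatives run, of 122 other list medians 68, of 5 Ifng ratios 2, and of 4 ratios of dividing cells 1. Except where stated, the cause was not tested. No paired analysis was possible because the libraries of a group are runs of 1 capture and replicate numbers pair nothing. The replicate block, DESeq2 and other fits planned for separate captures were not run. Leaving out a library also changes the averaged counts, the kept barcodes, the doublet calls and the clustering.

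The ranges in this paragraph come from runs of 1 capture and repeated clustering, so they are no spread between replicates. Leaving out each library gave share ratios of 1.64 to 1.88 for monocytes/macrophages, 0.640 to 0.822 for CD8 T and 0.914 to 1.23 for CD4 T. Genes at least 2-fold higher numbered 38 to 80 in CD8 T and 61 to 103 in CD4 T. The interferon gamma list lay at -0.80 to -0.57 and the type I list at -2.76 to -2.26 in CD4 T, and the type I list at -1.57 to -1.47 in monocytes/macrophages. Naive and memory genes in CD8 T lay at -0.36 to 0.58. The Ifng ratio was 1.14 to 1.41 in CD8 T and 1.79 to 2.47 in CD4 T, and the ratio of dividing CD8 T cells 1.16 to 1.43.

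At 200 genes per cell the monocyte/macrophage share ratio was 1.56 and its type I list -1.47. At 20% mitochondrial counts the type I list was -1.62 in monocytes/macrophages and -1.74 in neutrophils, MHC class II turned to 0.19 in CD8 T, and the ratio of dividing cells was 0.725 in CD4 T and 0.481 in NK.

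Without integration the share ratio was 1.69 for monocytes/macrophages and 0.825 for CD8 T, and 42 genes were 2-fold higher in CD8 T. The interferon gamma list was -0.51 in CD8 T, the type I list -1.49 in monocytes/macrophages, and the Ifng ratio 1.14 in CD8 T. Reversed were MHC class II in CD4 T (0.0892), naive and memory genes in CD8 T (0.64), regulatory T genes in CD4 T (-0.0605), inflammatory (0.43) and neutrophil (0.43) genes in NK, and proliferation (-1.02) and Arg1 (0.54) in monocytes/macrophages.

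At resolution 0.5 the share ratio was 1.64 for monocytes/macrophages and 0.827 for CD8 T, 39 genes were 2-fold higher in CD8 T, and 15 higher and 64 lower in Treg. The type I list was -1.48 in monocytes/macrophages and the Ifng ratio 1.14 in CD8 T. Naive and memory (0.56) and tissue repair genes (-0.14) reversed in CD8 T. At resolution 2 CD4 T had a share ratio of 0.895, 109 genes 2-fold higher, an interferon gamma list of -0.58, a type I list of -2.27 and an Ifng ratio of 2.40.

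As shares of lymphoid or of myeloid cells only, ratios were 1.45 for monocytes/macrophages, 0.189 for neutrophils, 0.235 for B, 0.918 for CD8 T, 1.68 for CD4 T, 1.75 for Treg and 1.64 for NK cells, and 1.13 for all T cells, reversed. The other denominator makes this change. With the Ear2-led cluster the monocyte/macrophage ratio was 2.07.

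Removing the top doublet scores gave 218 genes 2-fold higher in CD8 T, type I medians of -2.28 in CD8 T and -1.68 in NK, and an Ifng ratio of 1.18 in CD8 T. It reversed MHC class II in CD8 T (2.63) and CD4 T (0.29), and inflammatory (0.37) and macrophage genes (2.05) in CD8 T.

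Median-of-ratios scaling gave 33 genes higher and 275 lower in CD8 T, 34 and 81 in CD4 T, and 18 and 79 in NK, and H2-Ab1 in monocytes/macrophages at 0.0185. A minimum of 20 UMIs counts more genes by construction, 220 higher and 654 lower in CD8 T, 221 and 252 in CD4 T, 95 and 289 in Treg, 184 and 218 in NK, 316 and 810 in monocytes/macrophages, and 140 and 696 in neutrophils. Without the 3 top cells of each gene there were 20 and 120 in CD8 T, 10 higher in CD4 T, 2 and 14 in Treg, 9 and 14 in NK, 104 higher in monocytes/macrophages and 3 in neutrophils, and the Ifng ratio was 1.24 in CD8 T, 1.35 in CD4 T and 0.760 in NK, where this leaves out knockout cells only.

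List members with at least 50 UMIs gave interferon gamma medians of -0.50 in CD8 T and -0.0237 in Treg and a type I median of -0.69 in NK. They reversed tissue repair in CD8 T (-0.11) and NK (-0.00219), inflammatory genes in NK (0.15) and complement and lysosome in Treg (-0.0890). With no minimum neutrophil genes in NK were 0.55. Without markers of another class, regulatory T genes in CD4 T were -0.27 and inflammatory genes in NK 0.15. Without the dividing cluster, CD8 T proliferation was -0.16 and the Ifng ratio 1.76. Thinning put the Ifng ratio of shares at 1.71 in CD8 T and 2.28 in NK, and unthinned cells put the ratio of dividing CD8 T cells at 1.04.

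Depth limits the small classes, with 70 knockout Treg cells and 117 neutrophils.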

Other observations

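The lists below were planned, and the doublet removal was chosen after the results were seen. Immediate early and dissociation genes were higher in the knockout capture, with 13 of 16 higher and 0 lower in CD8 T, 14 higher and 1 lower in NK, and 10 higher and 5 lower in neutrophils (median 0.37). In monocytes/macrophages (0.15, 10 higher and 4 lower) the list did not stand apart from random lists (percentile 97.2). Oxidative phosphorylation genes were lower, with medians of -0.26 in CD8 T, -0.38 in CD4 T, -0.54 in Treg, -0.30 in NK and -0.28 in monocytes/macrophages, against -0.07 in neutrophils. Genes of the unfolded protein and stress responses were higher in CD8 T (0.61). They did not stand apart from random lists in monocytes/macrophages (0.25, 6 of 8 higher, percentile 97.4), and did not differ detectably in neutrophils (-0.24, -0.70 to 0.16). Lymphocyte recruiting chemokines were lower in monocytes/macrophages (-0.65), with 9 of 10 lower and 1 higher. Regulatory T genes stood at 0.21 (0.05 to 0.31) in Treg cells, at percentile 90.4 of random lists. Complement and lysosome genes stood at 0.18 in monocytes/macrophages (8 of 12 higher and 4 lower), and did not stand apart from random lists (percentile 97.4).

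Sphingolipid synthesis genes of the host cells differed little in lymphocytes once the class median was taken off, at -0.04 in CD8 T, 0.15 in CD4 T, 0.09 in Treg and 0.01 in NK cells, beside 0.36 in monocytes/macrophages and 0.16 in neutrophils. MHC class II transcripts in CD8 T cells stood at -0.64 and macrophage free RNA at -0.37 in the same cells, but doublet removal reversed both (2.63 and 2.05), so neither is read as a difference. The erythroid list had fewer than 3 measurable genes in each class and gave no result.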
